A study of Prunus sibirica with 6 samples.

How the data were processed

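Flower buds of 2 clones of Prunus sibirica, the Siberian apricot, were profiled by RNA sequencing. Clone 595 has abortive pistils and clone 28 has normal pistils. Each clone has 3 libraries, which the study describes as biological replicates. Whether the replicates came from separate trees or from separate buds of the same tree is not stated, so the p-values measure only the spread between these libraries. Clone and pistil type coincide throughout: no clone contributed both kinds of pistil, and the comparison is between 2 genotypes as much as between 2 pistil types. Whole buds were ground, so each value is an average over all tissues of the bud.

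The values used are FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library), which the authors deposited as 1 table of 34055 genes and 6 libraries, with no other normalization recorded in the file. Per the submitters' processing notes, HISAT2, Picard, SAMtools 0.1.18, GATK and edgeR were used. Their roles and order, the quantifier, the genome build and the gene annotation are not given in the sources used here. Total RNA was extracted and libraries were made by a standard Illumina protocol, per the labels' protocols; whether they keep the strand is not given, so overlapping and antisense genes cannot be told apart. Of the identifiers, 32790 are gene models of the form PaF106G and 1265 are marked as new genes. The table does not pair identifiers with gene names or products, and no annotation was used here. The 21 gene lists that had been fixed by product name (floral organ identity, anther and pistil markers, hormones, cell cycle and others) therefore could not be applied, and no result is given for them. All columns of the table belong to the 6 libraries.

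Because FPKM are not counts, the main test was made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, over the 18904 genes with a mean of at least 1 FPKM across the 6 libraries. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 changes are abortive minus normal pistil on the log2(FPKM + 1) scale, which understates the change of genes with low values. Fold thresholds were applied on the same scale. Genes listed at 0 in all 3 libraries of one clone and with at least 1 FPKM in every library of the other were counted without a test. Shares of new and reference gene models were compared with two-sided Fisher's exact tests, in which genes are treated as independent although they are not. With 3 libraries against 3, a permutation of the labels for a single gene cannot give a p below 0.1, so no permutation test is given for single genes.

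The depth of the libraries is not recorded in the table and could not be recovered from it. Where whole reads are counted, low values share steps between libraries. Among genes below 0.2 FPKM in both of 2 libraries, at most 0.562% of the ratios fell within any window 0.1% wide in the 15 pairs of libraries, against 25.5% in simulated whole reads. No counting interval or detection limit is therefore given, and the number of replicates sets the precision: the median standard error of a log2 change was 0.11. An exact 0 is reported as listed at 0, since it can be a failed estimate as well as an absence of reads.

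The test was checked on simulated data made from the real gene means and within-clone spreads of the 18904 tested genes, of which 200 were changed. It recovered 52.0% of the genes changed 1.5-fold, 88.0% of those changed 2-fold and 98.0% of those changed 4-fold. Unchanged genes made 1.75% of its calls. Far fewer genes changed there than the 44.0% called in the real data, which alters the adjusted threshold. The noise was also drawn independently for each gene and library, so these shares need not hold for the real calls.

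The main test, its thresholds and the rule for genes named in the text were fixed before the data were examined. So were the count of genes listed at 0, the similarity of libraries and the alternatives, except where stated. For identifiers without names, the rule takes the 2 highest and the 2 lowest log2 changes among called genes whose libraries do not overlap between clones and that have a mean of at least 5 FPKM in the higher clone. The alternatives were the replicate number as a block, pseudocounts of 0.1 and 0.01, no filter and a minimum mean of 5 FPKM, rescaling to TPM, scaling by the median log ratio of genes present in every library, quantile normalization, no intensity trend, library weights, an adjusted p under 0.01, and leaving out each library in turn. The comparisons of new with reference genes, the classes of expression level and the order of identifiers were not among the tests fixed before the data were examined. The comparison of large changes in new and reference genes within classes of level was added after seeing the data. The labels number the replicates 1 to 3 in both clones. Deviations from the clone means correlated at -0.04, -0.07 and -0.03 between same-numbered libraries, so over all tested genes the numbers were not taken to pair them.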

Results

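Gene expression in flower buds was measured by RNA sequencing in 2 clones of Prunus sibirica. Clone 595, with abortive pistils, was the treatment group and clone 28, with normal pistils, was the control group, with 3 libraries each. Summed FPKM ranged from 624935 to 639355 per library. Between 24797 and 25136 genes were above 0 in a library, and between 18408 and 18850 reached 1 FPKM. The 10 most abundant genes took 2.73% to 3.19% of the summed FPKM of a library, so no library was dominated by a few transcripts.

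The first comparison asked how far the clones differed against the spread between replicates. The same set of genes made up most of the bud transcriptome of both clones: 17685 genes had a mean of at least 1 FPKM in both, 914 reached it only in the abortive pistil clone and 1082 only in the normal pistil clone. Of the 100 most abundant genes of each clone, 74 were shared. Expression levels over all tested genes separated the clones clearly. Across the 18904 tested genes, libraries of the same clone correlated with a mean Pearson's r of 0.9903 (0.99 to 0.9909 over 6 pairs) and libraries of different clones with a mean r of 0.9373 (0.9333 to 0.941 over 9 pairs). The corresponding mean Spearman's rho was 0.9905 within clones and 0.9415 between them. These correlations are across genes, which are not independent replicates, and no test was attached to them. The first principal component held 81.0% of the variance and placed the 3 abortive pistil libraries between -44.1 and -38.6 and the 3 normal pistil libraries between 40.8 and 42.4.

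**Figure D1:**
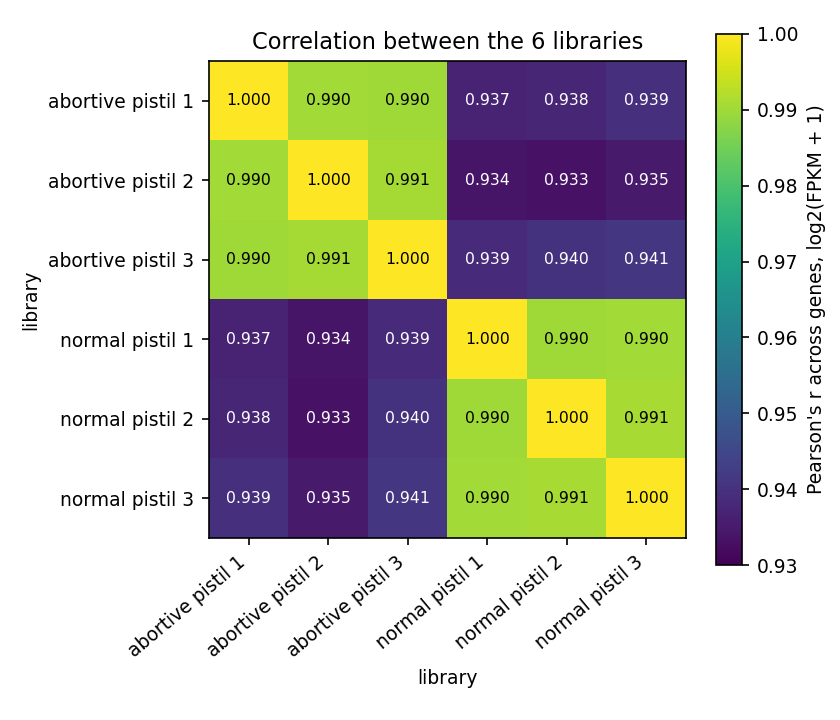
Pearson's r across the 18904 tested genes between each pair of the 6 libraries, on log2(FPKM + 1); both axes list the libraries by clone and replicate, and colour gives r. The 6 pairs within a clone lie at 0.99 or above, and the 9 pairs between clones lie between 0.9333 and 0.941.

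The main comparison asked which genes differed between buds with abortive and with normal pistils. In the abortive pistil clone 3328 genes were higher and 4988 were lower than in the normal pistil clone, 8316 of 18904 tested genes or 44.0% (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small. The median absolute log2 change of a called gene was 0.52, with quartiles of 0.37 and 0.80, against a median standard error of 0.11 over all tested genes. Changes of at least 2-fold were seen in 1369 called genes, 630 higher and 739 lower. This count was 2065 with a pseudocount of 0.1, 2143 with 0.01 and 633 with a minimum mean of 5 FPKM. At least 4-fold changes were seen in 129 genes that rose and 169 that fell, and at least 16-fold changes in 12 that rose and 17 that fell. The libraries of the clones did not overlap in 10363 genes, 54.8% of those tested, where chance gives 10%; 8119 of the called genes were among them.

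The split between higher and lower genes depended on how the libraries were scaled. On the FPKM as deposited, 60% of the called genes were lower in the abortive pistil clone, and the median log2 change of all tested genes was -0.07. After each library was scaled by its median log ratio, 4153 genes were higher and 4089 lower, so 49.6% were lower, and after quantile normalization 50.7% were lower. In the fit with median log ratio scaling 7416 of the 8316 genes were called again, all in the same direction. Changes of at least 2-fold then numbered 698 higher and 659 lower.

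**Figure D2:**
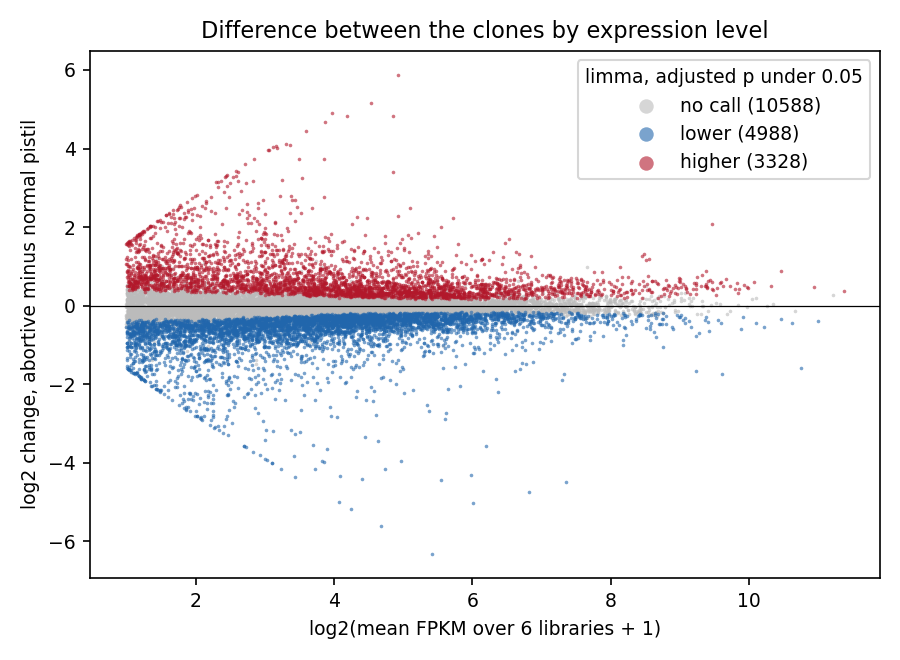
Log2 change (abortive minus normal pistil, vertical axis) against log2 of the mean FPKM over 6 libraries plus 1 (horizontal axis) for each tested gene, coloured by whether it was called higher (3328), called lower (4988) or not called in limma. The largest changes lie at low and middle levels; the straight outer edges are genes near 0 in one clone.

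Genes of every expression level were among those that changed, but the size of the change fell with the level. Of the 5138 genes with a mean of 1 to 5 FPKM, 44.1% were called and 14.3% were called with at least a 2-fold change. Of the 5584 genes with 20 to 100 FPKM, 44.1% were called and 2.99% changed at least 2-fold. The 1234 genes with 100 FPKM or more, the most abundant transcripts of the bud, were called in 49.3% of cases and changed at least 2-fold in 1.86%, 8 of them higher and 15 lower. Direction also varied with level. Genes called lower made 64.1% of the calls at 5 to 20 FPKM (1911 lower and 1072 higher genes) and 47.2% at 100 FPKM or more, where 321 rose and 287 fell. After scaling by the median log ratio these shares of the calls were 53.4% and 31.8%, the latter from 363 higher and 169 lower genes.

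**Figure D3:**
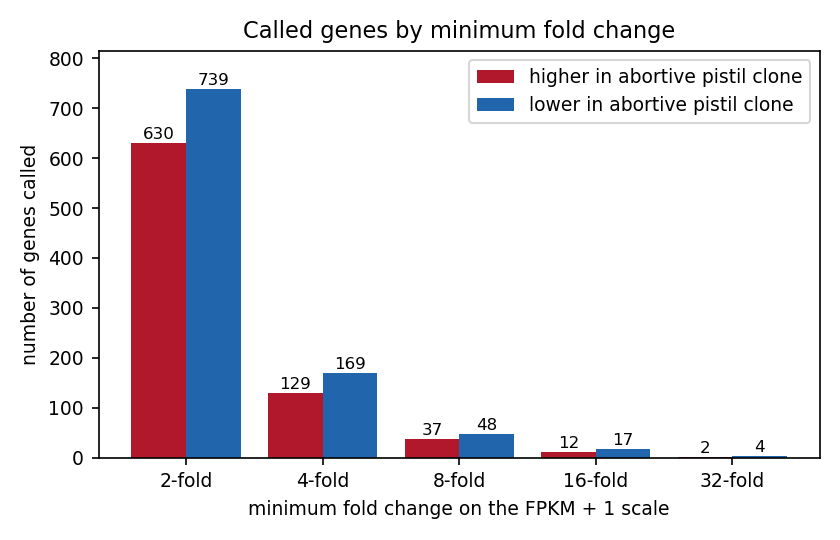
Number of genes called higher (red) and lower (blue) in the abortive pistil clone (vertical axis) at increasing minimum fold change on the FPKM + 1 scale (horizontal axis), in limma at an adjusted p under 0.05. From 630 higher and 739 lower genes at 2-fold, the counts fall to 2 and 4 at 32-fold; with median log ratio scaling the 2-fold counts are 698 higher and 659 lower.

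The genes with the most extreme changes were close to absent in one clone and clearly expressed in the other. The identifiers carry no names in the deposited table, so the 2 most raised and the 2 most lowered genes are given by identifier. PaF106G0500019567.01 was at 61.0, 57.7 and 56.6 FPKM in the abortive pistil libraries (58.5 ± 2.26, SD, n = 3) and at 0.0169, 0.0132 and 0 FPKM in the normal pistil libraries. Its log2 change was 5.88 with a standard error of 0.10 (limma, adjusted p = 1.14e-09). PaF106G0600021731.01 was at 44.3 ± 1.03 FPKM (SD, n = 3) with abortive and 0.275 ± 0.0545 FPKM (SD, n = 3) with normal pistils. That is a log2 change of 5.15 with a standard error of 0.10 (limma, adjusted p = 2.14e-09). In the other direction, PaF106G0300012159.01 was at 90.7, 79.2 and 80.6 FPKM in the normal pistil libraries (83.5 ± 6.28, SD, n = 3). It was listed at 0, 0 and 0.173 FPKM in the abortive pistil libraries, a log2 change of -6.32 with a standard error of 0.11 (limma, adjusted p = 1.14e-09). PaF106G0400015292.01 was at 51.9, 41.1 and 55.1 FPKM with normal pistils (49.4 ± 7.37, SD, n = 3) and was listed at 0, 0 and 0.056 FPKM with abortive pistils. Its log2 change was -5.62 with a standard error of 0.13 (limma, adjusted p = 6.29e-09). With a pseudocount of 0.1 the changes of these genes were 9.06, 6.90, -9.22 and -8.73 in the same order, so their size depends on the pseudocount and their direction does not.

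**Figure D4:**
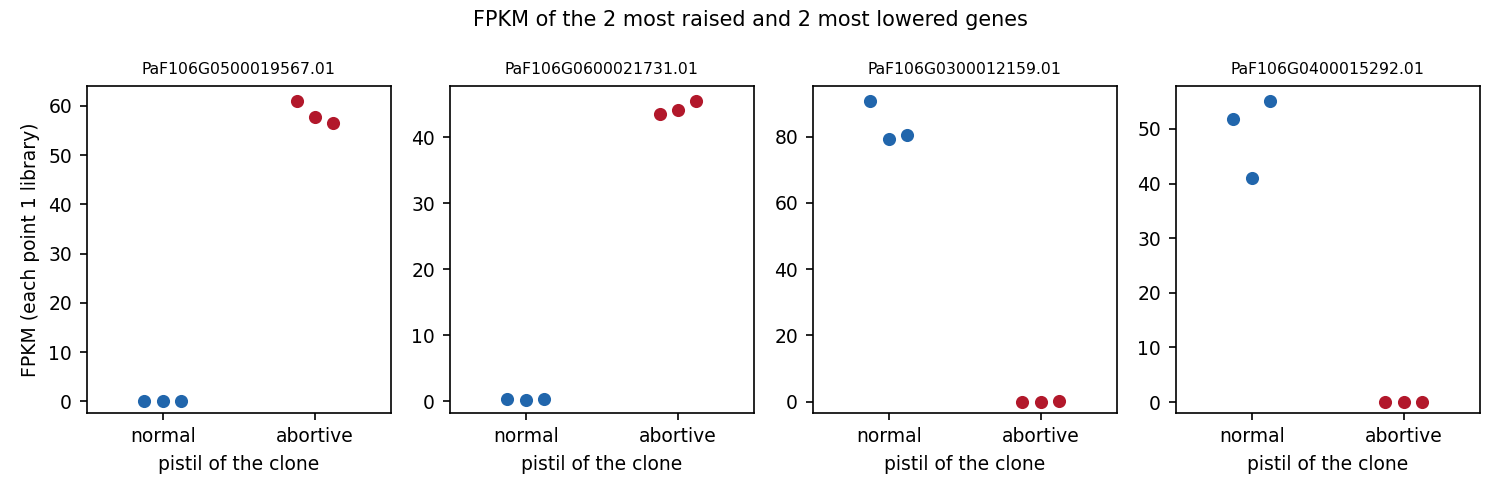
FPKM (vertical axis, a separate linear scale from 0 in each panel) of the 2 most raised and the 2 most lowered genes in the normal (blue) and abortive (red) pistil clones; each point is 1 library. In PaF106G0500019567.01 the 3 abortive pistil libraries sit between 56.6 and 61.0 FPKM, and in PaF106G0300012159.01 the 3 normal pistil libraries sit between 79.2 and 90.7 FPKM, with the other clone near 0.

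A further group of genes was listed at 0 in all libraries of one clone. In the abortive pistil clone 82 genes were listed at 0 that had at least 1 FPKM in every normal pistil library, where their median level was 2.64 FPKM and the highest 19.6 FPKM. In the normal pistil clone 66 genes were listed at 0 that had at least 1 FPKM in every abortive pistil library, with a median of 2.56 and a highest level of 29.3 FPKM. Together these 148 genes were 0.782% of the 18931 genes with at least 1 FPKM in every library of a clone. No fold is given for them, since the table holds no counts. Of the 148, 105 passed the filter of the main test and all 105 were called. The rule for listing them already requires libraries that do not overlap between clones, so these calls are not separate evidence. With a minimum of 5 FPKM in the other clone, 20 and 14 genes remained.

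The genes marked as new, outside the reference gene models, were compared with the reference genes. They were called about as often: 214 of 490 tested new genes (43.7%) and 8102 of 18414 reference genes (44.0%), an odds ratio of 0.987 with a 95% interval of 0.82 to 1.19 (Fisher's exact test, p = 0.927). Large changes were more frequent among the new genes. At least 2-fold changes were called in 72 new genes (14.7%) and in 1297 reference genes (7.04%), an odds ratio of 2.27 with an interval of 1.73 to 2.95 (Fisher's exact test, p = 8.37e-09). Within 5 classes of expression level, a comparison added after seeing the data, this odds ratio was 1.78 with an interval of 1.36 to 2.32 (Mantel-Haenszel). New genes were also more often listed at 0 in one clone, 22 of 506 (4.35%) against 126 of 18425 (0.684%), in both directions: 10 were at 0 in the abortive and 12 in the normal pistil clone. The odds ratio was 6.60 with an interval of 3.96 to 10.5 (Fisher's exact test, p = 6.65e-11), and 3.13 with an interval of 1.95 to 5.03 within 5 classes of level (Mantel-Haenszel). The new genes in this comparison were expressed at lower levels, with a median of 3.96 FPKM in the higher clone against 14.5 FPKM for the reference genes.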

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

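The alternatives for the correlations and the principal component were chosen after seeing the data. No gene called in the main test changed sign under any alternative in which it was tested. The replicate block, the fit without an intensity trend and the stricter adjusted p leave each log2 change as it was. Those alternatives could therefore not change a sign. The 4 genes named by identifier kept their direction and stayed called in every alternative run for them. These alternatives were the replicate block, a pseudocount of 0.1, both rescalings and each library left out. The 1369 calls of at least 2-fold rose to 2065 with a pseudocount of 0.1 and 2143 with 0.01 (1147 and 1200 of them lower), because a smaller pseudocount compresses low values less. They fell to 633 (305 higher, 328 lower) with a minimum mean of 5 FPKM, where 13766 genes were tested. An adjusted p under 0.01 left 5381 calls, 3162 of them lower. The block of replicate numbers, which were not taken to pair the libraries, gave 7663 calls, 7475 of them shared with the main test. In the correlations of deviations, no library was closest to the same-numbered library of the other clone. Leaving out one library at a time gave 6553 to 7750 calls (2603 to 3238 higher, 3864 to 4923 lower) and 1362 to 1432 of at least 2-fold (584 to 670 higher, 692 to 848 lower). Of the genes listed at 0 in one clone, a minimum of 5 FPKM in the other kept 34 (20 at 0 with abortive and 14 with normal pistils). Allowing up to 0.1 FPKM in place of 0 gave 221, with 103 on the normal pistil side. Leaving out a library gave 163 to 174, a count that could only rise because the rule then covers fewer libraries. The mean r was 0.9845 within and 0.8933 between clones with a pseudocount of 0.1, and 0.994 and 0.9678 without the filter; the first component then held 82.0% and 77.7% of the variance, and 81.4% to 82.7% when a library was left out. The cause of these shifts was not tested. Gene list tests were not run, since no products are paired with the identifiers. Depth is unknown, so a limit of detection cannot be given for low genes.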

Other observations

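Of the tests below, the counts of called genes under other splits, the shares by level class after scaling, the windows of identifiers and the group of variable genes were chosen after the result was seen. Among reference genes, large changes lay next to each other in the order of the identifier numbers. The numbers run without overlap through 8 groups of identifiers; that they follow the order of genes in the genome is an assumption, which the table does not state. Among the 18414 tested reference genes in this order, 197 pairs of neighbours were both called with at least a 2-fold change in the same direction, against a mean of 45.8 and a highest value of 68 in 1000 shuffles of the positions (permutation p = 0.001, the smallest these permutations can give). There were 30 runs of 3 or more such neighbours, against at most 6 in 200 shuffles. Identifiers that were not tested were skipped, so neighbours can lie several numbers apart. The shuffles did not hold expression level fixed, although large changes were more frequent at low levels. The longest run held 6 genes of identifier group 4, all lower in the abortive pistil clone, with a median level of 24.2 FPKM in the normal and 0.00301 FPKM in the abortive pistil clone; it includes one of the most lowered genes, PaF106G0400015292.01. A run of 5 genes in group 1 was higher, with medians of 31.8 FPKM with abortive and 6.64 FPKM with normal pistils, and a run of 4 in group 3 was lower, with 4.85 against 38.0 FPKM. The ratio to the shuffled mean was 4.30 for these large changes and 1.11 for called genes under 2-fold. The latter had 1469 same-direction neighbours against a shuffled mean of 1319.1 and a highest value of 1420, so they were clustered too. The sets held 1297 and 6805 genes, and a ratio has less room to rise in the larger set. The ratios therefore do not compare the strength of clustering.

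Several explanations were set against this clustering, and the count of opposite pairs was chosen after the result was seen. Reads moving from one near-identical neighbour to another would leave neighbours changed in opposite directions. There were 57 such pairs, within the shuffled range of 25 to 68 (mean 45.6), so its part in those pairs stays open. The bound set beforehand, on the share of opposite pairs, was not used, because the same-direction pairs alone lower that share. Genes near absent in one clone, as from a deletion or a diverged sequence, were strongly clustered (22 same-direction pairs against a shuffled mean of 0.7). Genes under this cut do not make the whole pattern: graded changes, with at least 0.1 FPKM in the lower clone, gave 138 pairs against at most 53 in shuffles. The graded genes still include some close to absent, such as PaF106G0600021731.01 at 0.275 against 44.3 FPKM. The cut therefore cannot separate a deletion or a diverged sequence from a graded change. Windows of 100 identifiers with at least 15 large changes numbered 8, of which 3 lay in group 2 and 5 in group 8. Shuffling blocks of 20 neighbours gave 4.04 on average and up to 10 (permutation p = 0.03). Short local clusters alone thus reached the observed number in few shuffles. The windows were chosen after the result was seen, so this p-value does not settle whether long stretches or short local clusters made them. Reads of 1 expressed gene spread over several copies, blocks of sequence that differ between the clones and neighbours regulated together may each contribute, and stay open without sequences or names.

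The 148 genes listed at 0 in one clone form a second pattern. Zeros also occurred within clones: 13 genes with abortive and 7 with normal pistils were at 0 in at least 1 library and at 5 FPKM or more in another of the same clone. Failed estimates falling at random over libraries would, however, put similar numbers at 0 under other splits of the 6 libraries, and the other 9 splits gave at most 3. The lower level of new genes does not account for all of their excess among these genes: within 5 classes of level the odds ratio fell from 6.60 to 3.13, with a 95% interval of 1.95 to 5.03 (Mantel-Haenszel). A candidate explanation is that new gene models built from these libraries include loci carried or transcribed by one clone; this, a sequence difference of a clone from the reference and a true loss of expression were not tested.

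The excess of lower over higher genes in the abortive pistil clone is the third pattern. Scaling by the median log ratio brought the lower share from 60% to 49.6%, but that scaling centres the genes and so fixes the outcome; whether the excess reflects the authors' scaling cannot be told apart from a real excess on that value. After scaling, 31.8% of the calls were lower at 100 FPKM or more (exact 95% interval 27.8% to 35.9%) and 55.1% at 1 to 5 FPKM (53.1% to 57.2%). The classes also differed before scaling. The median log2 change was -0.10 at 1 to 5 FPKM, -0.09 at 5 to 20 FPKM and -0.01 at 100 FPKM or more. On the FPKM + 1 scale a single factor would shift low classes no more than high ones. The class medians went the other way, but their spread between libraries was not measured. The shares after scaling were read after the same centring, and their intervals treat genes as independent. Whether a single scale factor was the whole cause, or a part of it, therefore stays open. A difference between the clones in bud composition was not tested.

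The split of the libraries by clone gave 8316 calls, and the highest of the other 9 splits gave 2; for calls of at least 2-fold these were 1369 and 2. In each case 1 of the 10 splits, the real one, gave as many, and with 10 splits a share under 0.05 cannot be reached.

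A few lowered genes differed widely between replicates. Of the genes called at least 2-fold lower, 6 also spanned at least 4-fold among the abortive pistil libraries on the FPKM + 1 scale, which leaves out genes near 0 that span more on FPKM itself. Their median FPKM was 3.57, 0 and 10.5 in abortive pistil replicates 1, 2 and 3, and 75.5, 41.6 and 85.1 in the normal pistil replicates. In 5 of the 6, replicate 3 was the highest and replicate 2 the lowest in both clones. Same-numbered libraries thus followed one order in these genes, unlike over all tested genes, where their deviations correlated at -0.04, -0.07 and -0.03; the genes were picked for their range, and no test was made. Such a range was not confined to the lowered genes, and its frequency was not tested. Only the abortive pistil libraries were examined for it. It was seen in 6 of the 739 genes called at least 2-fold lower. It was also seen in 1 of the 630 genes called at least 2-fold higher and in 23 of the other tested genes. Of those 23, 1 had replicate 3 highest and replicate 2 lowest in both clones. Other orders shared by the clones were not counted.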
